A study of Oidiodendron maius Zn with 6 samples.

How the data were processed

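RNA of free-living mycelium of the fungus Oidiodendron maius Zn was sequenced after 45 days of growth on agar plates of a modified Melin-Norkrans medium at pH 4.7, amended with glucose (1 g per L), with BSA (0.1 g per L) or with peat (approximately 10 g dry weight), per the labels' protocols. There were 6 libraries, 2 for each of 3 conditions, made of 75 bp reads on an Illumina MiSeq. In each condition 1 library had paired reads and 1 had single reads. The recipe in the labels lists glucose in the basal medium. Whether glucose and ammonium were also present in the BSA and peat plates is not given in the sources used here, and the labels use the code NH4 in the titles of the glucose libraries.

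Each library had a deposited table of 16703 gene models, identified by JGI protein IDs of the Oidma1 annotation, per the file headers. The deposited counts are the unique gene reads and the total gene reads of each model, per the file headers. Both columns held whole numbers, and the unique count never exceeded the total. The RPKM values were deposited by the authors beside these counts. Solving each RPKM for the length gave 1 whole-number length per model in all 90022 values with at least 1 read, within a tolerance of 0.01 nt, so the authors' RPKM was scaled to the sum of total gene reads in the file. These lengths had a median of 1203 nt, and 68.1% were multiples of 3, so they were not coding lengths alone. The trimming, aligner, counter, their versions and the treatment of the mates of a pair are not given in the sources used here.

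The files do not pair the protein IDs with gene names, and no annotation was used here. The 25 gene lists written before the data were examined (carbohydrate-active enzymes, peptidases, transporters, stress genes and others) were defined by product names or protein signatures. Hence 0 of them could be filled, and no set test was run. The rule for unnamed models therefore applied. For each comparison the 2 higher and the 2 lower models with the largest absolute log2 fold change were named, among models with an adjusted p under 0.05, the same direction in both read layouts and a mean of at least 20 CPM in the higher condition. Other models are named only where a result singles them out, and these were chosen after their values were seen.

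The main fit was written before the data were examined. It was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on total gene reads of all 6 libraries, with TMM factors, filterByExpr by condition (14497 models tested), condition and read layout as terms, 2 residual degrees of freedom and Benjamini-Hochberg adjustment. CPM values were divided by TMM-scaled library sizes.

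The 2 libraries of a condition were compared before any fold change was read. A read layout effect common to the 3 conditions was removed for each model, and the remaining deviations of the unique reads were set against binomial sampling with a chi-square statistic. Over 10373 models with at least 5 expected reads in every paired-read library, the statistic was 1.06 per degree of freedom, where sampling alone gives 1. It was 36.3 and 42.7 when each paired-read library was matched with the single-read library of another condition. Without removal of the layout effect it was 1.75 for glucose, 2.11 for BSA and 1.83 for peat. The coefficient of variation that edgeR estimated beyond counting was 1.57%. The libraries of a condition therefore differed by little more than sampling noise, and they were counted as 1 sample. The read layout marks a shared kind of library in all conditions and was kept as a block.

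With 1 sample per condition, the edgeR test compares these libraries and not the carbon sources, and its adjusted p-values hold no spread between cultures. The test was run on simulated data to show this. With sequencing noise alone, 200 models with a mean of at least 20 CPM were changed 1.5-fold in BSA. The test recovered 100% of them in BSA against glucose (14117 models tested) with 10 false calls. In peat against glucose, where nothing was changed, it called 0. With cultures that varied at random by 10% and no effect of the carbon source, it called 4155 models in BSA against glucose (14113 tested). With 20% it called 7991 (14114 tested), and each of these 2 settings was simulated in 1 draw. Models are therefore reported by size of change. The rule, chosen after the libraries had been compared, was at least 4-fold by the fitted fold change with at least 20 CPM in the higher condition. A fold of a named model is the ratio of its normalised reads summed over the 2 libraries, with an exact (Clopper-Pearson) 95% interval. A condition with 0 reads was given 3 reads, over its 2 libraries together, to obtain a lower bound. Intervals and bounds cover counting error only.

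Alternatives fixed before the data were examined were a fit without the layout block, DESeq2 1.42.0, limma-voom, RLE size factors, 2 other filters on low counts, the 4 libraries of a comparison alone, removal of the 20 most abundant models, thinning to the shallowest library, an added 2-fold limit, and leaving out each library. Unique reads, total count scaling and removal of a gene length trend (loess on log2 length in each library) were added after the data were seen.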

Results

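Transcript levels were measured in Oidiodendron maius Zn, an ascomycete that forms mycorrhiza with plants of the heather family, grown without a host on glucose, on bovine serum albumin (BSA, a protein) or on peat (partly decayed plant matter). Each condition had 1 paired-read and 1 single-read library. The paired-read libraries held 969553 gene reads for glucose, 893061 for BSA and 1043870 for peat. The single-read libraries were far deeper, with 22021177, 20008329 and 24690601 gene reads. Of the 16703 gene models, 14789 had at least 10 reads in the glucose single-read library, 14482 in that of BSA and 14727 in that of peat. A count of 0 in the single-read libraries allowed a share of reads of up to 1.36e-05% for glucose, 1.5e-05% for BSA and 1.22e-05% for peat.

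The 2 libraries of a condition gave nearly the same profile. After removal of a layout effect common to all conditions, their deviations were 1.06 times the variance expected from sampling (10373 models), against 36.3 and 42.7 times when libraries of different conditions were matched. Among models with at least 500 expected reads in every paired-read library the value was 1.27 (136 models). The 2 libraries of a condition were therefore counted as 1 sample (n = 1), although the labels do not say whether they came from separate cultures. No comparison below has a replicate check, and the differences are those between 3 samples.

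The most abundant transcript differed in share between the conditions. The model with protein ID 208821 (852 nt), singled out after its values were seen as the model with the highest mean CPM, took 3.46% of the reads in BSA (95% exact interval 3.45 to 3.46), 1.46% in peat (1.46 to 1.47) and 0.473% in glucose (0.47 to 0.476). Its normalised level was 8.16-fold higher in BSA than in glucose (interval 8.1 to 8.21) and 3.25-fold higher in peat than in glucose (3.23 to 3.28). The 10 most abundant models of each library together took 10.7% of the reads in the BSA single-read library, 6.42% in that of peat and 4.69% in that of glucose. In the paired-read libraries these shares were 8.79%, 6.13% and 4.74%. Reads in BSA were thus more concentrated on few models in both layouts. The shares include reads that match more than 1 model, which made up 2.09% of the BSA single-read library and 0.309% of that of glucose.

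The comparison of BSA with glucose set plates with a protein at 0.1 g per L against plates with sugar at 1 g per L. Kind and amount of the amendment changed together and cannot be told apart. Whether the BSA plates also held glucose or ammonium is not given in the sources used here. Most models differed little. Of the 8483 models with at least 20 CPM in either condition, 91.7% lay within 2-fold. At least 4-fold differences were found for 96 models, 73 higher and 23 lower in BSA. Of these, 40 were at least 8-fold higher and 3 at least 8-fold lower in BSA. All 96 had the same direction in both read layouts, which was no separate check. The models were selected on these same libraries, and the 2 layouts were counted as 1 sample. The models with the largest increases were nearly silent on glucose. Protein ID 20533 (714 nt) had 118 CPM in BSA against 0.165 in glucose, from 2327 and 4 reads, a 714-fold difference with a counting interval of 278 to 2623. Protein ID 20508 (821 nt) had 104 CPM against 0.206, from 2056 and 5 reads, a 505-fold difference (216 to 1556). The largest decreases were smaller in size. Protein ID 184808 (436 nt) had 74.1 CPM in glucose and 4.65 in BSA, 15.9-fold lower in BSA (12.9 to 19.9). Protein ID 134334 (387 nt) had 36.2 CPM in glucose and 2.73 in BSA, 13.3-fold lower (10.1 to 17.8). The size of some of these differences rested on 1 library. Without the glucose single-read library, glucose had 0 reads of 20533 and 20508, which were then at least 39.6-fold and 35-fold higher in BSA, and 134334 was 5.81-fold lower (3.1 to 10.3). Without the BSA single-read library 134334 was 15.6-fold lower by summed reads (4.29 to 129), from 2 reads in BSA, while its fitted log2 fold change went from -3.72 to -2.81, short of 8-fold. In peat these 2 models had intermediate levels of 32 and 18.2 CPM. The other model at least 8-fold lower in BSA, protein ID 19143 (557 nt, named after its values were seen), had 658 CPM in glucose and 77.6 in BSA as means of the 2 libraries. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 9210 of the 14497 models tested (4234 higher and 4976 lower), which compares these libraries and not the carbon sources. It called 3006 without the glucose single-read library and 2928 without that of BSA. The higher share of calls was 46% with TMM factors and 31.6% with total count scaling, which moved the median log2 fold change by -0.16. That share was 51.6% without the 20 most abundant models and 55% with DESeq2, so the direction with more calls depended on the setting. The count of 23 lower models depended on the setting, at 46 without the BSA single-read library and 13 with the gene length trend removed.

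The comparison of peat with glucose addressed growth on plant-derived organic matter, where kind and amount of the amendment again changed together. Here 132 models differed at least 4-fold, 68 higher and 64 lower in peat. All 132 had the same direction in both layouts, which again was no separate check. At least 8-fold differences numbered 33 higher and 26 lower. Within 2-fold lay 93.2% of the 8492 models with at least 20 CPM in either condition. Protein IDs 20533 and 20508 had the largest increases in this comparison too. They reached 143 and 149 CPM in peat, 865-fold (338 to 3178) and 722-fold (309 to 2224) above glucose. The largest decreases in peat exceeded those in BSA in fold. Protein ID 20072 (606 nt) had 54.6 CPM in glucose and 0.271 in peat, 201-fold lower (97.5 to 502), and 90.3 CPM in BSA. Protein ID 20077 (718 nt) had 464 CPM in glucose and 2.56 in peat, 182-fold lower (143 to 235), and 418 CPM in BSA. Without the peat single-read library, peat had 0 reads of both, which were then at least 18.9-fold and 161-fold lower. Without the glucose single-read library, 20533 and 20508 were at least 48-fold and 50.01-fold higher in peat. The edgeR quasi-likelihood test on reads called 9006 models (4437 higher and 4569 lower), with the same limit to these libraries. The higher share of calls was 49.3% with TMM factors, 40.9% with total count scaling and 54.7% with DESeq2. The test called 2626 without the glucose single-read library and 2654 without that of peat.

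**Figure D1:**
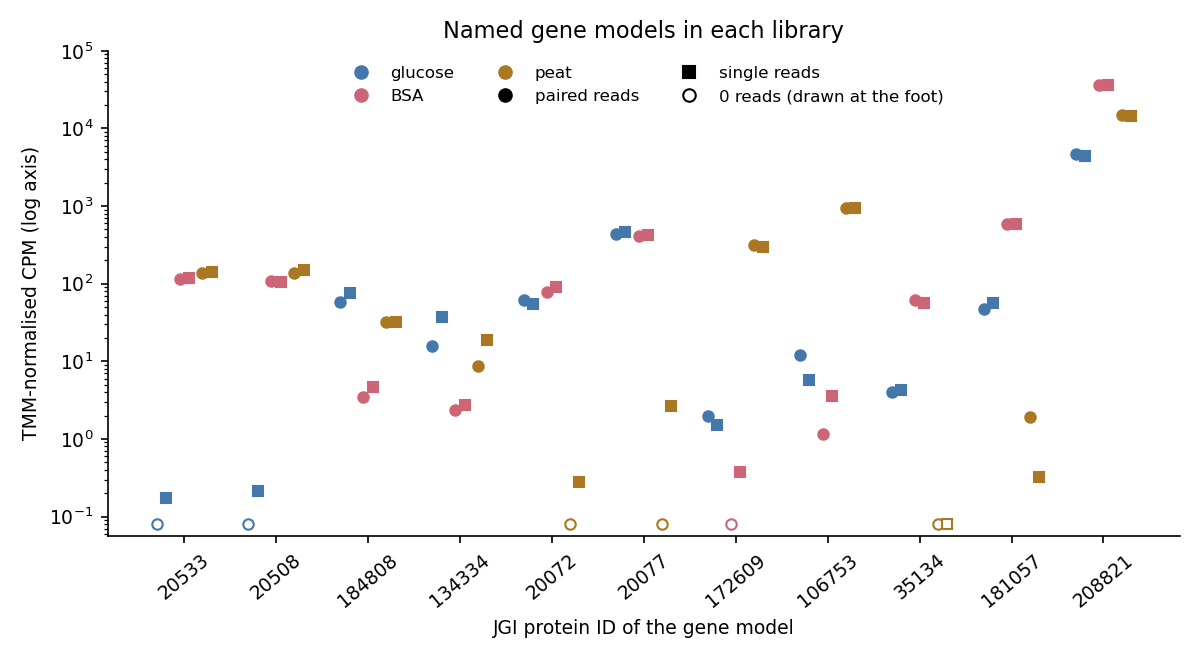
TMM-normalised CPM (log axis) of the 10 models named by the fixed rule and of the most abundant model (208821), for each of the 6 libraries; colour gives the condition and marker shape the read layout, and open markers at the foot stand for 0 reads. The 2 libraries of a condition lie close together except at low counts, and protein ID 181057 is at 587 CPM in BSA against 0.387 in peat.

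The direct comparison of peat with BSA found 141 models with at least 4-fold differences, 63 higher and 78 lower in peat. All 141 had the same direction in both layouts, here too no separate check. In peat, 27 models were at least 8-fold higher and 37 at least 8-fold lower. The models with the largest increases in peat were low in both other conditions. Protein ID 172609 (595 nt) had 295 CPM in peat, 0.354 in BSA and 1.52 in glucose, 832-fold above BSA (404 to 2071). Protein ID 106753 (1840 nt) had 943 CPM in peat, 3.49 in BSA and 5.93 in glucose, 270.3-fold above BSA (213 to 347). Protein ID 35134 (1473 nt) had 1112 reads in BSA and 0 in peat, at least 484-fold lower in peat, and stood at 4.2 CPM in glucose. Protein ID 181057 (1741 nt) had 587 CPM in BSA, 0.387 in peat and 56.6 in glucose, 1515-fold lower in peat than in BSA (824 to 3161). Without the peat single-read library, 181057 was 305-fold lower (84.5 to 2520.1) from 2 reads in peat, and 35134 at least 19.5-fold lower. Without the BSA single-read library, 172609 was at least 84.4-fold higher in peat, and 106753 was 810.3-fold higher (145 to 32005) from 1 read in BSA. The edgeR quasi-likelihood test on reads called 7095 models, of which 50% were higher in peat. That share was 64.3% with total count scaling and 42.8% without the 20 most abundant models. The number of calls was 3932 without the layout block, 1697 without the BSA single-read library and 1723 without that of peat.

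Sorted over all 3 conditions by the same 4-fold limit, 40 models were lower in peat than in both others and 25 were higher in peat than in both others. In BSA, 20 models were higher and 11 lower than in both others. Relative to both others, glucose had 29 models lower and 6 higher. The 29 were the models at least 4-fold higher in BSA and in peat alike, of which 19 were at least 8-fold higher in both. With at least 20 CPM in the higher condition of each comparison, 4 models were at least 4-fold higher in BSA and at least 4-fold lower in peat, and 0 showed the opposite. These 4, named after their values were seen, were protein IDs 55538, 136373, 146269 and 181057, with log2 fold changes from 2.3 to 3.38 in BSA and from -7.15 to -2.35 in peat. Independent lists of these lengths would share 0.572 higher and 0.17 lower models, where 29 and 6 were shared. Both comparisons use the same glucose libraries, which alone give a correlation above 0. With sequencing noise alone, simulation of unchanged conditions gave a Pearson r across genes of 0.487 between the fold changes and a covariance of 0.0129. With cultures varying at random by 20% it gave an r of 0.495 and a covariance of 0.0979 in 1 draw. Only 0.6 simulated models (mean of 5 draws) changed at least 4-fold in BSA with sequencing noise alone and 1 with cultures varying by 20%, so the simulation gives no chance value for the 29 shared models. The observed r was 0.52 and the covariance 0.312. A covariance grows with the spread of the fold changes. The observed log2 fold changes had standard deviations of 0.764 in BSA and 0.784 in peat, which the simulation was not set to match. The higher observed covariance therefore cannot be read as a shared response. With the gene length trend removed, r was 0.483, below both simulated values of r, and the covariance was 0.269. Without the glucose single-read library r was 0.726, without that of BSA 0.385 and without that of peat 0.41. The r of 0.52 was thus close to what shared controls alone gave in the simulation, and it is no evidence of a common response to BSA and peat. With 1 glucose sample the controls could not be split, and part or all of the overlap may come from the shared controls. Genes are not independent replicates, so no p is given.

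**Figure D2:**
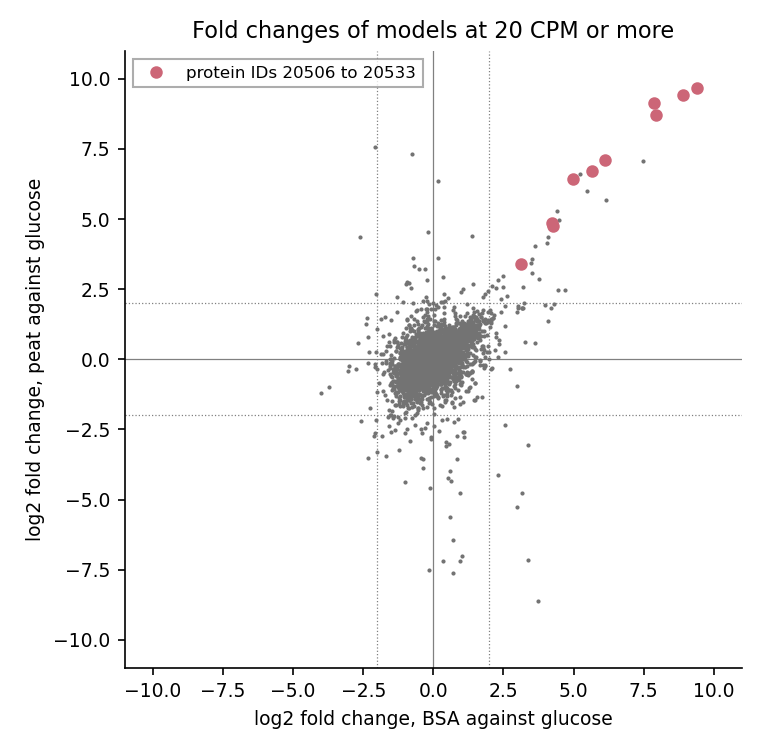
Fitted log2 fold changes of BSA against glucose (horizontal axis) and of peat against glucose (vertical axis) for the 8679 models with at least 20 CPM in any condition; dotted lines mark 4-fold, and red points are the models with protein IDs 20506 to 20533. Beyond 4-fold in both, 34 points lie at the upper right, 6 at the lower left, 7 at the lower right and 3 at the upper left, of which 29, 6, 4 and 0 had at least 20 CPM in the higher condition of each comparison.

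Gene model length moved with the fold changes against glucose. Models of up to 500 nt had a median log2 fold change of -0.48 in BSA and -0.42 in peat (319 models), and models over 3000 nt had 0.42 in BSA and 0.43 in peat (813 models). Of the models over 3000 nt, 87.1% were higher in BSA than in glucose and 89.7% higher in peat than in glucose. Between peat and BSA the medians of the same classes were 0.03 and -0.02. The medians of these classes differed by less than 2-fold. With the trend removed, the models at least 4-fold lower in BSA numbered 13 in place of 23, and the named 184808 and 134334 (436 and 387 nt) had log2 fold changes of -3.57 and -3.28 in place of -3.99 and -3.72.

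**Figure D3:**
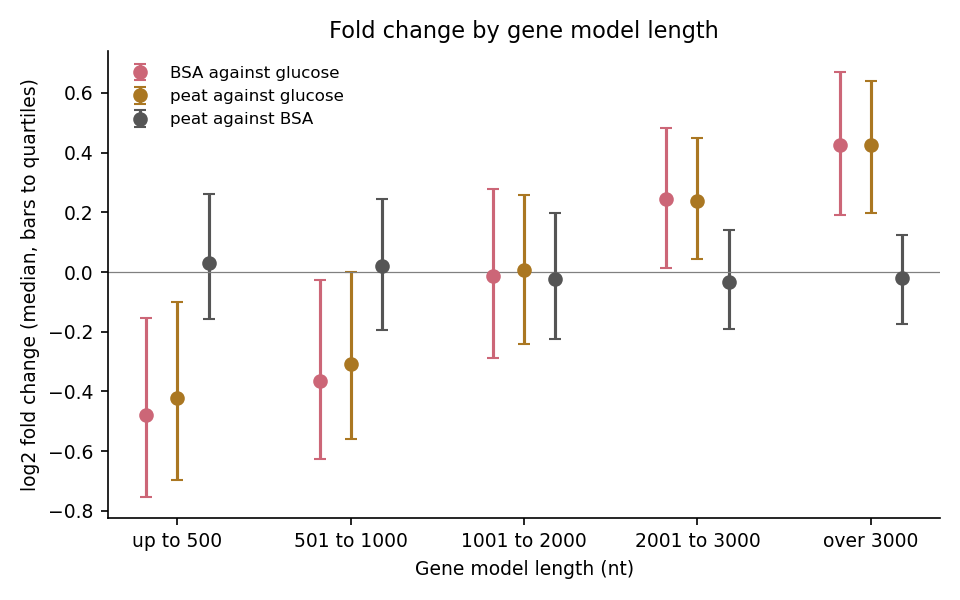
Median log2 fold change (points) and quartiles (bars) by gene model length in nt for the 3 comparisons, over models with at least 20 CPM in any condition. Both comparisons against glucose go from below 0 for models of up to 500 nt (-0.48 and -0.42) to above 0 for models over 3000 nt (0.42 and 0.43), and peat against BSA stays near 0.

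Protein IDs 20508 and 20533 belonged to a series of models with close ID numbers, which was noticed after the values were seen. In numeric order of the tested IDs, all 10 models from 20506 to 20533 were at least 4-fold higher in peat than in glucose, with log2 fold changes from 3.4 to 9.67 and a median of 6.91. Against glucose, the same 10 models were higher in BSA by log2 values between 3.11 and 9.39. Protein IDs 20072 and 20077 belonged to 4 models from 20072 to 20079 that were all lower in peat, with log2 fold changes from -7.6 to -5.64 against glucose and from -8.32 to -6.22 against BSA.

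**Figure D4:**
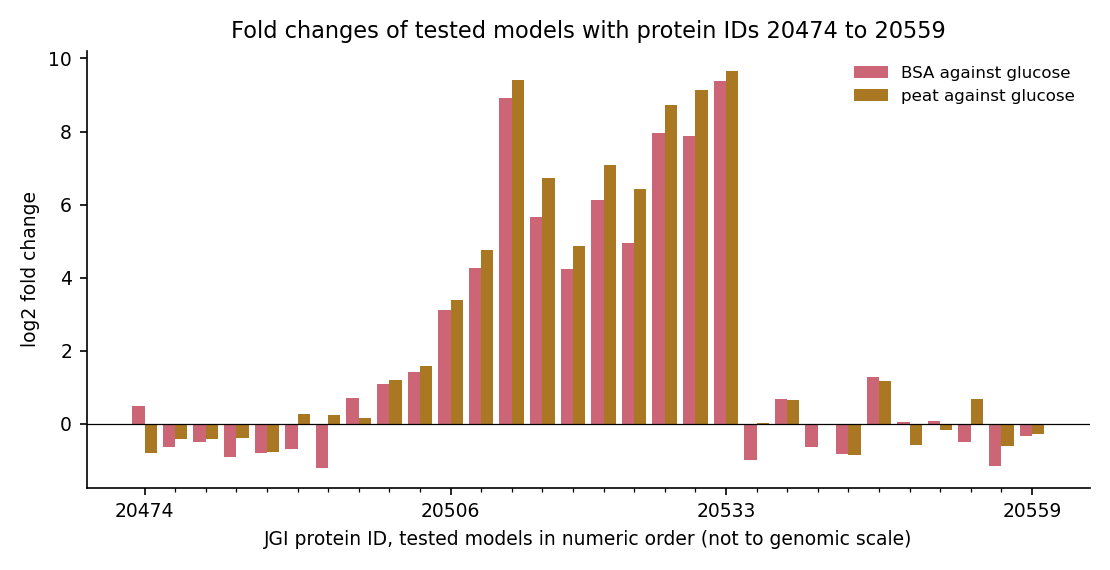
Fitted log2 fold changes against glucose of the 30 tested models with protein IDs from 20474 to 20559, drawn in numeric order of the ID and not to genomic scale; bars show BSA and peat. The 10 models from 20506 to 20533 stand at 3.11 or above in both conditions, and the 10 models on either side lie between -1.2 and 1.58.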

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

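Reads that match more than 1 gene model were looked at outside the main measurement, and both tests of them were chosen after their percentages had been seen. In BSA they made up 2.09% of the single-read library and 1.07% of the paired-read library, above the glucose libraries at 0.309% and 0.164%, with peat between them at 0.894% and 0.505%. A difference in read layout is argued against as the cause, because BSA exceeded glucose 6.53-fold in the paired-read libraries and 6.77-fold in the single-read libraries. The 4 models with the most such reads in the glucose libraries, which were also the 4 highest in BSA and in peat, held 81% of them in the glucose single-read library and 97.9% in that of BSA. Without these models the ratio of BSA to glucose was at most 0.788, so the excess in BSA lay in these 4 models. This ratio largely follows from the shares just given and is no separate check. Which models a read was shared between is not given, so it was not tested whether the 4 share reads with one another. These 4 models, of 204 to 459 nt (139570 is the longest), were 8.22-fold to 9.31-fold higher in BSA than in glucose and 3.5-fold to 3.57-fold higher in peat, close to the 8.16-fold and 3.25-fold of the most abundant model 208821. The levels of 139572 and 111751 are uncertain one by one, since they had no unique read in BSA. Of the BSA reads of 139577, 75.3% were shared. For 139570 only 8.64% of the BSA reads were shared, and it was 8.22-fold higher in BSA than in glucose. Whether the 4 models are a repeated sequence, and whether their higher level is a response to the carbon source, stay open and were not tested.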

How the results depend on the processing

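The tests on unique reads, total count scaling and the gene length trend were chosen after the data were seen; the others were fixed before. The direction of the named models held in all 216 values under the alternatives, but not their size. Their direction could hardly have changed, since these models were chosen for the largest fold changes in the same libraries. The fitted fold change of 10 of the 12 named values moved by over 1.5 times when 1 library was left out, and that of 7 under another alternative. In addition, 106 of the 108 counts of models beyond 4-fold stayed within 1.5 times. The exceptions were the models at least 4-fold lower in BSA than in glucose (23), at 13 with the gene length trend removed and from 21 to 46 when 1 library was left out, the highest without the BSA single-read library. Many alternatives, such as limma-voom, RLE size factors and the other filters, refit the same 6 libraries and hardly change a fitted fold change. Their 4-fold counts could therefore hardly have moved, and no alternative adds a second sample of a condition. The counts of edgeR calls, from a test whose error holds sequencing noise only, were lower after thinning and without a single-read library of the comparison. Leaving out 1 library gave 2928 to 9194 for BSA against glucose, 2626 to 9192 for peat against glucose and 1697 to 7181 for peat against BSA, the low values each time without a single-read library of the comparison (for BSA against glucose 3006 without that of glucose, for peat against glucose 2654 without that of peat, and for peat against BSA 1723 without that of peat). Here the lone paired-read library is assumed to vary like the others. Thinning to the shallowest library gave 3673, 3281 and 2189 calls. DESeq2 gave 3755, 3341 and 2120, and a 2-fold limit 1804, 1622 and 1457; the cause of the lower DESeq2 counts was not tested. In the fit with no replicate block (read layout left out), peat against BSA had 3932 calls, and the other 2 comparisons 6601 and 6040, within 1.5 times. The correlation of the BSA and peat fold changes ranged from 0.385 (without the BSA single-read library) to 0.726 (without the glucose single-read library); the cause was not tested. Set tests on the fixed gene lists were not run because the files pair no ID with a name, and the alternatives for files without counts did not apply. Depth limits the paired-read libraries, in which only 9270 to 9860 models had at least 10 reads.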

Other observations

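Of the tests in this part, that of the order of the protein IDs and the edgeR fit with the gene length trend removed were chosen after the result had been seen. Of the models with at least 20 CPM in another condition, 1 had at most 3 reads in peat, which was protein ID 35134, 1 had at most 3 reads in BSA, and 0 had at most 3 reads in glucose. The one in BSA, protein ID 126476 (1722 nt), had 3 reads in BSA, 24 in glucose and 535 in peat, and was named after its values were seen.

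In peat against glucose, 3 models in numeric order from 172600 to 172609 were also at least 4-fold higher, with log2 fold changes from 2.04 to 7.58. In BSA against glucose, 4 models from 139563 to 139577 were at least 4-fold higher, with log2 fold changes from 2.49 to 3.18, and 3 of these are among the models that share reads.

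Fold changes against glucose were higher for longer gene models, and peat against BSA did not show this. Read layout or depth is argued against, since the Spearman correlation across 8679 models was 0.409 or more in each layout and comparison against glucose. Short abundant genes alone, such as those of ribosomes, are also argued against, since the correlation was 0.376 or more among models over 1000 nt outside the tenth with the highest level. A length-dependent recovery of RNA in the glucose sample, for example from partly degraded RNA, is a candidate explanation, since the correlation was 0.353 or more in each of 5 equal groups by mean expression and -0.05 in peat against BSA. With 1 glucose sample, a true response of long genes to the carbon source stays open, and changes of under 2-fold against glucose may hold this trend (8345 edgeR calls for BSA with the trend removed, of which 7091 were among the 9210 of the unadjusted fit). The 4-fold lists were not free of the trend. With it removed, the models at least 4-fold lower in BSA went from 23 to 13, and those at least 4-fold higher from 73 to 78.

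Models with consecutive protein IDs had similar fold changes, with a Spearman correlation over 1618 pairs of 0.235 in BSA against glucose, 0.262 in peat against glucose and 0.203 in peat against BSA, and of 0.05, 0.01 and 0.05 for neighbours 21 to 50 apart. Chance order is argued against by a one-sided permutation p of 1e-05 in all 3 comparisons, the smallest that 100000 shuffles can give, for the highest shuffled value of 0.11. Reads shared between copies are argued against too, since at least 0.9996 of the correlation was left in the 1559 pairs of models without shared reads. Similar gene length is argued against in the comparisons against glucose, where at least 0.885 was left with the length trend removed. Peat against BSA had almost no length trend to remove, so its correlation could hardly change and decides nothing there. A hypothesis is that IDs close in number may lie close in the genome, so that the 10 models from 20506 to 20533 and the 4 from 20072 to 20079 would be clusters of neighbouring genes. The files give no positions, so this stays open and untested, but 1 gene split over a whole run would not give log2 fold changes in BSA from 3.11 to 9.39 over the 10 models, nor 20072 higher (90.3 against 54.6 CPM) and 20077 lower (418 against 464 CPM) in BSA than in glucose.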
